A study of Mus musculus with 12 samples.

How the data were processed

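Total RNA of 12 cultures of MP cells, a mouse model of MYC-driven Group 3 medulloblastoma, was measured on Affymetrix Mouse Gene 2.0 ST arrays, 1 array per culture. Per the labels, RNA was extracted with a Qiagen RNeasy kit, converted with an Ambion WT Expression kit and labelled with biotin by a GeneChip WT Terminal Labeling kit. The values deposited by the authors are log2 expression values, 1 per probe set. The log base is read from their range, 1.50 to 14.5. The processing notes name only Agilent Feature Extraction 10.7.3.1, a program for another maker's arrays, and how the values were summarised, background-corrected and normalised is not given in the sources used here. Array medians lay between 7.10 and 7.21, within the limit of 0.2 set for leaving the values as they were, so no further normalization was applied. The depth of an array has no count, and the number of arrays limits the precision.

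The value table held 41345 probe sets. By the annotation of the array, 23521 named 1 gene, 1814 named several and 16010 were not listed. Those naming several genes were not used here, and those not listed were tested apart. Gene names came from a RefSeq table of the mouse genome through Entrez numbers for 23328 probe sets, and 193 kept the annotation's own symbol. The build of the array annotation is not given in the sources used here, so no positions are printed. Where a gene had more than 1 probe set (1082 genes), the one with the highest mean was kept, which left 22180 genes. A gene was tested if its value lay above the array's 25th percentile of all probe sets on at least 3 of the 12 arrays. This kept 18652 genes and left out 3528. Of 584 gene symbols in the lists or named in advance, 522 had a gene on the array, 2 of them through a synonym. H1f0 and Trp53 had no probe set of their own and were not analysed here.

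Arrays were grouped by treatment and time as the labels give them, in 4 groups of 3. All comparisons came from 1 fit of the 4 group means with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend, 8 residual degrees of freedom). P-values are two-sided and Benjamini-Hochberg adjusted over the 18652 genes for each comparison, and a gene was called at an adjusted p under 0.05. The 6 comparisons were LBH589 against DMSO at 6 h, at 12 h and averaged over both, the difference between those effects, and 12 h against 6 h within DMSO and within LBH589. Comparisons that use the same arrays are not independent, in particular the change in DMSO and the LBH589 effect at 12 h, which share the DMSO 12 h arrays. No scan date or batch is given in the sources used here.

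The labels give each tumour 1 array in every group. Whether arrays of a tumour belong together was checked on their deviations from the group means. The 18 pairs of arrays of the same tumour correlated at 0.450 to 0.805, and those of another tumour and group at -0.51 to -0.0577. All 12 arrays correlated best with an array of their own tumour. The fit with the tumour as a block (6 residual degrees of freedom) was an alternative fixed in advance. Its values stand beside results where it changes a call or moves a count by more than 1.5 times. The fit without the block ignores this pairing and leaves the tumours' levels in the spread. It called fewer genes, 2948 against 6333 at 6 h, and all of the 2948 were also called with the block.

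A total of 34 gene lists were written from general knowledge, and the comparisons, tests, lists, alternatives and the rule for naming genes were fixed before the data were examined. Lists with at least 5 tested genes, 33 of them, were tested with limma's camera at a preset correlation of 0.01 and Benjamini-Hochberg adjusted over the lists. Camera compares a list with the other genes. Calls were repeated with an estimated correlation and with fry, which tests whether a list's genes move, on balance, one way. Lists overlap in some genes.

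By the naming rule, the text names the 8 largest rises and falls among called genes that moved the same way in all 3 tumours, for LBH589 at each time and over both. For changes with time it names the 5 largest called, and up to 4 called members of each list. Symbols without a descriptive name, microRNAs and small nucleolar RNAs were counted, not named, in the report. Hdac1 to Hdac11, Foxo1, Foxo3, Myc, Mycn, Cdkn1a, Cdkn1b, Bcl2l11 and Ccnd1 were always named. Of the genes the rule names, the text gives mainly those whose call held without each single array, a choice made after the values were seen. Of 96 called genes it names at 6 h, 54 met this, and of 106 at 12 h, 72. Leaving out each tumour as well, 28 and 47 kept their call. Genes named for the blocked changes with time, and genes of the closing section, were also chosen after their values were seen.

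Alternatives were the tumour as a fixed or random block, quantile normalization, centring of arrays on their medians or on reference genes, no filter or one at the 50th percentile, the mean of a gene's probe sets, every probe set, eBayes without a trend or robust, array weights, a fit of only the arrays compared, and leaving out each array and each tumour. Arrays and tumours were left out in the fit without the block. The procedure was tested on simulated data with the spread of these arrays and 18652 genes. Only 67, 67 and 66 genes were changed, by 0.5, 1 and 2 log2 units, and the noise was independent between genes. In the data many more genes were called at 6 h (2948), which loosens the adjusted threshold. The shares called and the false calls at 6 h may therefore be higher than those simulated. At 6 h, 16.4%, 83.6% and 95.5% of genes changed by 0.5, 1 and 2 log2 units were called, with 1 false call. With the block, 58.2%, 95.5% and 98.5% were called, with 10 false calls. For the difference between times, 3.0%, 32.8% and 95.5% were called without the block, with 0 false calls. With the block, 17.9%, 77.6% and 100% were called, with 4 false calls.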

Results

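Expression was profiled in cultured cells of a mouse model of MYC-driven Group 3 medulloblastoma, an embryonal tumour of the cerebellum. The cells, named MP, came from tumours in the cerebella of NSG mice, an immunodeficient strain. Cells of 3 tumours (MP525, MP567 and MP570) were treated with 25 nM LBH589, which is panobinostat, an inhibitor of histone deacetylases (HDACs), or with 0.00025% DMSO, the solvent. They were lysed after 6 or 12 h. Each tumour gave 1 array for each treatment and time, so each of the 4 groups held 3 arrays, 12 in all. The comparison of drug with solvent was made to learn how HDAC inhibition harms these cells. The values analysed were log2 expression values of an Affymetrix whole-transcript array. Array medians lay between 7.10 and 7.21, and any 2 arrays correlated at 0.965 to 0.991. The number of arrays limits the precision of every value below. Of 22180 genes with a named probe set, 18652 were bright enough to be tested. The first principal component held 44.4% of the variance and separated LBH589 from DMSO in every tumour. The second (22.3%) set MP567 apart from the other tumours, and the third (12.9%) set MP525 apart from MP570.

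LBH589 blocks HDAC enzymes and does not remove their transcripts, so no transcript level checks the treatment labels directly. Transcripts of the FOXO1 transcription factor and of the cell cycle inhibitor p21 (Cdkn1a) were both higher in LBH589 at 6 h and at 12 h. Foxo1 rose from 7.75 ± 0.20 in DMSO to 9.42 ± 0.28 in LBH589 at 6 h (log2 values, mean ± SD, n = 3), and from 7.89 ± 0.27 to 9.40 ± 0.23 at 12 h. These differences were 1.67 ± 0.19, adjusted p = 0.000246, and 1.51 ± 0.19, adjusted p = 0.000368 (log2 fold change ± SE, limma), which are 3.19-fold and 2.85-fold. Foxo3, another member of the family, had log2 fold changes of 0.17 and -0.05 that did not pass the test. Cdkn1a rose by 1.76 ± 0.49 at 6 h and 1.70 ± 0.49 at 12 h (limma adjusted p = 0.0312 and 0.0321), from DMSO levels that spread widely between tumours (10.52 ± 0.94 at 6 h). With the tumour as a block, these adjusted p were 3.3e-06 and 3.6e-06. The Cdkn1a call at 6 h was lost without the LBH589 array of MP525 (adjusted p = 0.0967), that of MP570 (0.105) or the DMSO array of MP567 (0.103). At 12 h it was lost without the same 3 kinds of array (0.0901, 0.0996 and 0.112), and at both times with every probe set tested on its own. Bcl2l11, which encodes the pro-apoptotic protein BIM, rose by 1.01 ± 0.11 at 6 h and 0.80 ± 0.11 at 12 h (limma adjusted p = 0.000233 and 0.000702). Ccnd1, which encodes cyclin D1, changed by -1.04 ± 0.28 and -1.06 ± 0.28 (limma adjusted p = 0.0254 and 0.0196). Its call at 6 h was lost without the DMSO array of MP525 (0.0816) or MP570 (0.0937), or the LBH589 array of MP525 (0.0836), MP567 (0.058) or MP570 (0.0548). At 12 h it was lost without the DMSO array of MP525 (0.0675) or MP570 (0.0792), or the LBH589 array of MP525 (0.0735). Without MP525 or MP570 as a whole, neither Cdkn1a nor Ccnd1 was called at either time. These omissions, like all others below, were made without the block, so differences in level between tumours stayed in the spread. A lost call therefore does not show that the effect differed between tumours. All 2948 genes called at 6 h without the block, Ccnd1 among them, were also called with it.

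**Figure D1:**
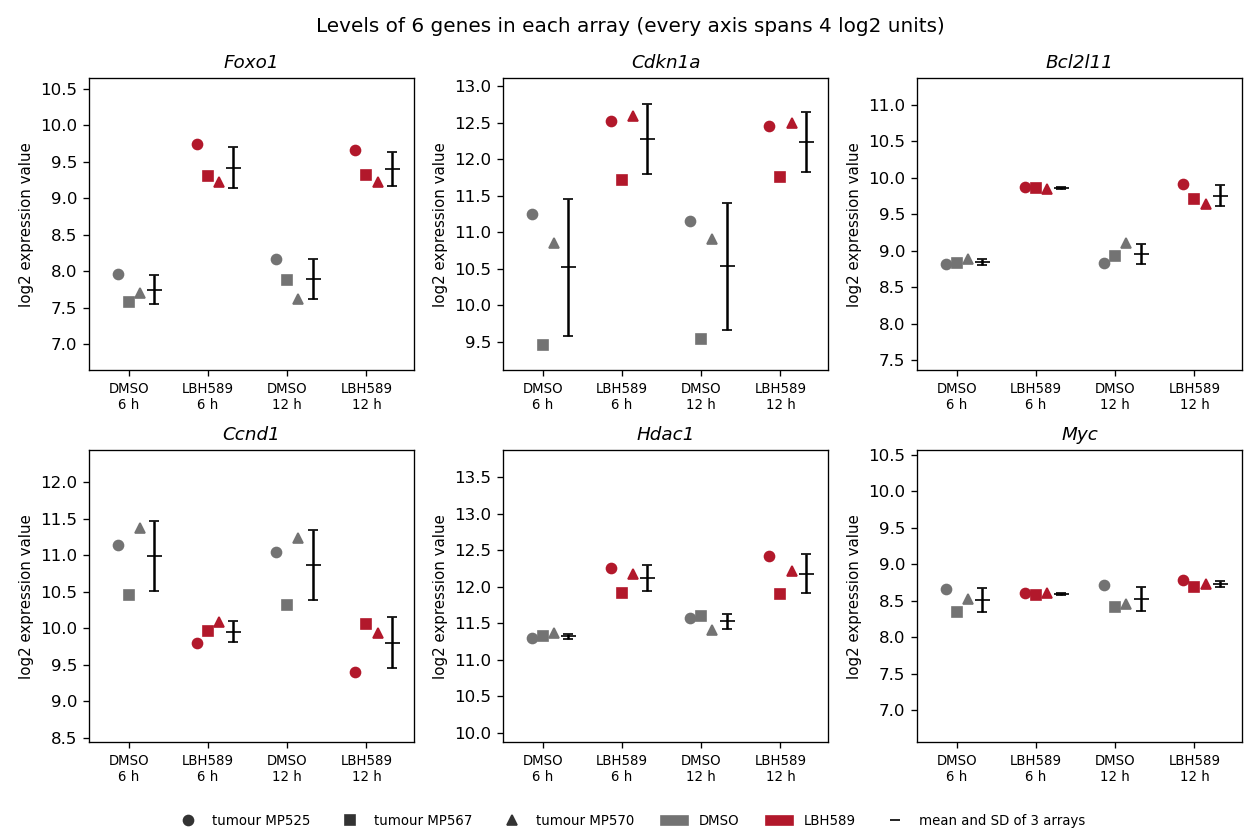
Log2 expression values of Foxo1, Cdkn1a, Bcl2l11, Ccnd1, Hdac1 and Myc in each of the 12 arrays, by treatment and time, with the tumour shown by the symbol and the mean and SD of the 3 arrays of a group in black. The LBH589 arrays of Foxo1 (means of 9.42 and 9.40) lie above every DMSO array of that gene (means of 7.75 and 7.89), while the Myc means lie between 8.51 and 8.73 in all 4 groups.

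Myc, the driver of the model, had log2 values of 8.51 ± 0.16 and 8.60 ± 0.01 in DMSO and LBH589 at 6 h, and 8.52 ± 0.16 and 8.73 ± 0.04 at 12 h (mean ± SD, n = 3). Its log2 fold changes of 0.09 ± 0.12 and 0.21 ± 0.12 did not pass the test (limma adjusted p = 0.697 and 0.26). Mycn had 0.29 and 0.33 (adjusted p = 0.178 and 0.111), and was called higher only with the tumour as a block (0.0449 and 0.0217). Cdkn1b, which encodes p27, had -0.45 and -0.40 (adjusted p = 0.0805 and 0.105), and was called lower with the block (0.00288 and 0.00528). Among the HDAC genes themselves, Hdac1 rose by 0.79 ± 0.13 and 0.66 ± 0.13 and Hdac11 by 0.86 ± 0.13 and 0.93 ± 0.13 at 6 and 12 h (limma adjusted p = 0.00207, 0.00495, 0.00138 and 0.000754). The Hdac1 call was lost at 6 h without MP570 (0.0674) and at 12 h without MP525 (0.0636) or MP570 (0.126), and that of Hdac11 at 6 h without MP525 (0.0501). Hdac5 rose by 0.78 ± 0.21 and 0.68 ± 0.21 (0.0271 and 0.0431). That call was lost at 6 h without the DMSO array of MP525 (0.101) or MP567 (0.0744) or the LBH589 array of MP567 (0.0771) or MP570 (0.103). At 12 h it was lost without any of 8 of the 12 arrays (highest adjusted p = 0.151), and with arrays centred on their medians. Leaving out MP567 or MP570 as a whole ended the Hdac5 call at 6 h (0.17 and 0.112) and at 12 h (0.214 and 0.152). Hdac3 rose by 0.30 ± 0.08 at 6 h (0.0325) and had 0.19 at 12 h, which was called with the block (0.0262). Its 6 h call was lost with arrays centred on their medians, and without any of 5 of the 12 arrays (highest adjusted p = 0.104, without the LBH589 array of MP525). That call was lost too without MP525, MP567 or MP570 as a whole (0.217, 0.122 and 0.0674). With the block and all arrays, both Hdac3 and Hdac5 were called at 6 h. Hdac2 (-0.20 and -0.29), Hdac6 (0.41 and 0.33), Hdac9 (-0.64 and -0.80) and Hdac10 (-0.37 and -0.30) were called only with the block. Their blocked adjusted p were 0.0373 and 0.00446, 0.00749 and 0.027, 0.00415 and 0.000741, and 0.0138 and 0.0359. Hdac4 (0.16 and 0.11), Hdac7 (0.04 and -0.03) and Hdac8 (0.24 and 0.05) were called in neither fit.

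After 6 h, Cpt1a and the HSP70 genes stood among the largest rises in LBH589. Cpt1a, which encodes the rate-limiting enzyme of fatty acid import into mitochondria, went from 7.66 ± 0.33 in DMSO to 10.35 ± 0.11 in LBH589 (log2 values, mean ± SD, n = 3). Its log2 fold change was 2.69 ± 0.21 (limma adjusted p = 4.4e-05). Slc8b1, a mitochondrial sodium-calcium exchanger, rose by 2.24 ± 0.12, and Gas6, a ligand of the TAM receptor tyrosine kinases, by 2.11 ± 0.18. The HSP70 genes Hspa1a (2.45) and Hspa1b (2.35) rose too, but they are nearly identical in sequence, so their probe sets may not tell them apart. Rhbdf2 (2.0) and Tspan17 (2.05) were also among the largest rises. The largest falls were those of Olig3, a neural progenitor transcription factor (-2.45 ± 0.32), and Acsl5, an enzyme that activates long-chain fatty acids (-2.38 ± 0.13). Ubxn8 (-2.21), Casd1 (-2.16), Arhgap42 (-2.00), Bend3 (-1.97), Zfp428 (-1.77) and Slc35f2 (-1.75) followed. Adjusted p of all these genes lay between 6.0e-06 and 0.00608, and each moved the same way in all 3 tumours. The call of Slc35f2 was lost without MP525 (0.119).

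In all, 2948 of the 18652 genes (15.8%) changed at 6 h at a limma adjusted p under 0.05, 1584 higher and 1364 lower in LBH589. With a log2 change of at least 1, these were 318 and 211. Of the 2948, 2947 moved the same way in all 3 tumours. With the tumour as a block, 6333 genes were called, 3349 higher and 2984 lower, among them all of the 2948. Direction shares depended on how arrays were scaled, with 1163 higher and 1760 lower after centring each array on its median, and 1994 higher and 1072 lower after centring on commonly used reference genes. Leaving out the LBH589 6 h array of MP525 gave 1929 calls and that of MP570 gave 1811, and leaving out all arrays of MP525 or MP570 gave 1018 and 879. Of 96 called genes given by the naming rule at 6 h, 54 kept their call without each single array, and 28 kept it also without each tumour.

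Of 33 gene lists fixed beforehand, camera called 7 at 6 h at a preset correlation of 0.01, and none with an estimated correlation. Fry, which asks another question, called 17, all of the 7 among them. Of 29 MYC target and ribosome biogenesis genes, 0 rose and 14 fell (0 and 17 adjusted over the list alone, 3 and 17 with the tumour block). They included Gnl3 (-1.10), Srm, which encodes spermidine synthase (-0.81), Wdr43 (-0.79) and Mybbp1a (-0.77). For this list camera's adjusted p was 4.1e-07 (adjusted p = 0.0593 with an estimated correlation). Of 20 immediate early genes, 5 rose and 0 fell (6 and 0 adjusted over the list alone, 14 and 0 with the tumour block), with Egr1 (1.44), Atf3 (1.02), Junb (0.98) and Egr2 (0.58) among them. Here camera's adjusted p was 0.000126 (adjusted p = 0.0593 with an estimated correlation). Of 27 FOXO factors and FOXO target genes, 9 rose and 0 fell (9 and 1 adjusted over the list alone, 14 and 2 with the tumour block). Besides Foxo1 and Bcl2l11, Gadd45b (1.77) and Sesn3 (1.05) rose, and camera's adjusted p was 0.000528 (adjusted p = 0.0593 with an estimated correlation). Of 14 histone acetyltransferase and bromodomain genes, 1 rose and 5 fell (1 and 8 adjusted over the list alone, 1 and 10 with the tumour block). Kat6b (-0.73) and Kat5 (-0.56) were among those that fell, and camera's adjusted p was 0.00334 (adjusted p = 0.0593 with an estimated correlation). Of 19 pro-apoptotic genes, 6 rose and 1 fell (8 and 1 adjusted over the list alone, 10 and 2 with the tumour block). Casp9, the initiator caspase of the mitochondrial pathway, rose by 0.73, whereas Bak1, an effector of outer membrane permeabilisation, changed by -0.93. The call of Bak1 was lost without any of 4 arrays (highest adjusted p = 0.0927, without the LBH589 array of MP570). It was lost too without MP525, MP567 or MP570 as a whole (0.176, 0.0597 and 0.0534). With the block and all arrays, Bak1 was called at 6 h. For the list camera's adjusted p was 0.00385 (adjusted p = 0.0742 with an estimated correlation). Of 17 cell cycle inhibitors, 5 rose and 0 fell (7 and 1 adjusted over the list alone, 11 and 1 with the tumour block), Cdkn1a and Gadd45b among them. There camera's adjusted p was 0.00493 (adjusted p = 0.0678 with an estimated correlation). Of 15 interferon response genes, 0 rose and 4 fell (0 and 4 adjusted over the list alone, 2 and 6 with the tumour block). Usp18, a protease that removes ISG15 (-1.29), and Ifit1 (-0.92) were 2 of them. For the list camera's adjusted p was 0.0302 (adjusted p = 0.469 with an estimated correlation), and it was not called with the tumour as a block (0.0677) or under a stricter filter on dim genes (0.067). Single arrays ended that call too, with adjusted p of 0.0527, 0.0695 and 0.0538 without the LBH589 array of MP525, the DMSO array of MP570 and the LBH589 array of MP570, and 0.0696 without MP525 as a whole. Leaving out 1 tumour also ended the calls of Mybbp1a, Atf3, Junb, Egr2, Sesn3, Kat6b, Kat5 and Usp18 at this time. Of the 7 lists, 4 were higher and 3 lower. With the block 9 were called, adding cholesterol synthesis (0.0433), DNA replication and G1/S (0.0266) and mitosis and G2/M genes (0.0252), all lower, and 0 were called with the block and an estimated correlation together. Without MP570, 12 lists were called.

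After 12 h, the largest fall was that of the interferon response gene Usp18. It stood at 8.04 ± 0.23 in LBH589 against 11.46 ± 0.55 in DMSO (log2 values, mean ± SD, n = 3), a log2 fold change of -3.43 ± 0.28 (limma adjusted p = 3.5e-05). Ddx58, which encodes the RNA sensor RIG-I, changed by -2.32 ± 0.15, the antiviral ADP-ribosyltransferase gene Parp12 by -2.68 ± 0.26, and the immunity-related GTPase gene Irgm1 by -2.44 ± 0.32. The DMSO levels of Usp18, Ddx58 and Parp12 themselves rose between 6 and 12 h, as described for the solvent below. That of Irgm1 rose by 1.78, which was called only with the tumour as a block (limma adjusted p = 0.204, and 0.0128 with the block). Acsl5 (-2.44), Olig3 (-2.40), Ap4s1 (-2.29) and Arhgap42 (-2.09) completed the largest falls. In LBH589 at 12 h, 1 of the 3 Irgm1 values and 2 of the 3 Ap4s1 values lay under the 25th percentile of their arrays, and the other Irgm1 values at most 0.28 over it, so the size and rank of these falls are uncertain. The largest rise was again that of Cpt1a (3.02 ± 0.21, limma adjusted p = 1.6e-05). Hspa1b (2.76), Hspa1a (2.55), Copz2 (2.34), Slc8b1 (2.18), Gas6 (2.15) and Tspan17 (2.14) followed. Rian, a maternally expressed non-coding RNA of the imprinted cluster around Meg3, rose by 2.64 ± 0.60 (limma adjusted p = 0.01), a call lost without MP525 (0.115). Each of these genes moved the same way in all 3 tumours.

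At 12 h, 3395 genes (18.2%) changed at a limma adjusted p under 0.05, 1703 higher and 1692 lower, and 334 and 296 with a log2 change of at least 1. All 3 tumours moved the same way for 3393 of them. With the tumour as a block, 6928 genes were called, 3471 higher and 3457 lower, including 3394 of the 3395. After centring arrays on their medians the split was 1168 higher and 2371 lower. After centring on reference genes it was 2854 and 1160, a scaling that moved the median change of all genes from 0.01 to 0.12. Some of these reference genes (Gusb, Hprt and Ywhaz) were themselves called lower at 12 h, so this scaling need not be neutral. Without MP525 or MP570, 1682 and 1265 genes were called. Of 106 called genes given by the naming rule at 12 h, 72 kept their call without each single array, and 47 kept it also without each tumour.

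Without the block, all called genes of the mitosis, DNA replication and DNA repair lists were lower at 12 h, while none of these lists was called by camera with an estimated correlation. Of 25 mitosis and G2/M genes, 0 rose and 15 fell (0 and 19 adjusted over the list alone, 0 and 21 with the tumour block). The mitotic kinase gene Plk1 (-0.94) and the kinesin gene Kif20a (-0.76) were among them, and camera's adjusted p was 2.0e-08 (adjusted p = 0.288 with an estimated correlation). Of 26 DNA replication and G1/S genes, 0 rose and 10 fell (0 and 11 adjusted over the list alone, 2 and 19 with the tumour block). Rrm2 (-1.14) and Rrm1 (-0.80), the subunit genes of ribonucleotide reductase, fell, and camera's adjusted p was 3.4e-05 (adjusted p = 0.418 with an estimated correlation). Of 18 homologous recombination and DNA damage response genes, 0 rose and 8 fell (0 and 10 adjusted over the list alone, 0 and 14 with the tumour block). These included the checkpoint kinase genes Chek1 (-1.09) and Wee1 (-0.99), Xrcc5 (-0.90) and Fancd2 (-0.84), and camera's adjusted p was 5.6e-06 (adjusted p = 0.0842 with an estimated correlation). Plk1, Kif20a, Rrm2, Rrm1, Chek1, Xrcc5 and Fancd2 were already called lower at 6 h, though camera called none of these lists then without the block. Of those 6 h calls, only Plk1 and Chek1 held without each array and each tumour. Of 29 MYC target and ribosome biogenesis genes, 0 rose and 17 fell (0 and 18 adjusted over the list alone, 3 and 20 with the tumour block), among them Gnl3 (-1.03), Nme1 (-0.84) and Wdr43 (-0.71). There camera's adjusted p was 4.6e-08 (adjusted p = 0.0624 with an estimated correlation). Of 15 interferon response genes, 0 rose and 8 fell (0 and 12 adjusted over the list alone, 1 and 12 with the tumour block). Besides Usp18 and Ddx58, Oasl2 (-2.08) and Irf7, a transcription factor of the interferon response (-1.89), fell, and camera's adjusted p was 1.3e-07 (adjusted p = 0.0842 with an estimated correlation). Of 14 histone acetyltransferase and bromodomain genes, 0 rose and 6 fell (0 and 9 adjusted over the list alone, 1 and 10 with the tumour block), with Kat6b (-0.79) and Brd9 (-0.73) among them, and camera's adjusted p was 0.000552 (adjusted p = 0.0624 with an estimated correlation). Of 11 cholesterol synthesis genes, 0 rose and 3 fell (0 and 5 adjusted over the list alone, 0 and 8 with the tumour block), including Hmgcs1 (-0.76) and Sc5d (-0.66). For this list camera's adjusted p was 0.00859 (adjusted p = 0.532 with an estimated correlation), and it was also lost with fry (0.1) and without the LBH589 12 h array of MP567 (0.0756). Leaving out 1 tumour ended the calls of Kif20a, Rrm2, Wee1, Xrcc5, Gnl3, Brd9, Hmgcs1 and Sc5d at this time.

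In 6 other lists the called genes were mostly higher at 12 h. Camera called these lists at the preset correlation and none of them with an estimated one. Of 20 immediate early genes, 13 rose and 0 fell (17 and 0 adjusted over the list alone, 18 and 0 with the tumour block), and camera's adjusted p was 1.3e-07 (adjusted p = 0.0624 with an estimated correlation). Egr1 (1.51), Junb (1.26) and Atf3 (1.15) were among them. Of 27 FOXO factors and FOXO target genes, 11 rose and 0 fell (11 and 0 adjusted over the list alone, 15 and 3 with the tumour block), including Gadd45b (1.80), the thioredoxin inhibitor gene Txnip (1.54) and Sesn3 (0.84). For this list camera's adjusted p was 0.00102 (adjusted p = 0.0732 with an estimated correlation). Of 17 cell cycle inhibitors, 6 rose and 0 fell (8 and 1 adjusted over the list alone, 12 and 2 with the tumour block), with Cdkn1c, which encodes p57 (1.05), added to those named at 6 h. There camera's adjusted p was 0.00547 (adjusted p = 0.0842 with an estimated correlation). Of 19 pro-apoptotic genes, 7 rose and 1 fell (8 and 1 adjusted over the list alone, 10 and 1 with the tumour block). Bmf rose by 0.68 and Bak1 changed by -1.12, and camera's adjusted p was 0.00553 (adjusted p = 0.0842 with an estimated correlation). This call was lost without MP525 (0.0511). Of 15 genes widely described as induced by HDAC inhibitors, 4 rose and 0 fell (4 and 0 adjusted over the list alone, 10 and 3 with the tumour block), Cdkn1a and Txnip among them. For that list camera's adjusted p was 0.0376 (adjusted p = 0.11 with an estimated correlation). It was lost after centring on reference genes (0.0967), under a stricter filter (0.0701), and without the DMSO (0.0976) or LBH589 (0.0756) 12 h array of MP567 or all of its arrays (0.0618). Of 10 mature cerebellar neuron genes, 3 rose and 0 fell (3 and 0 adjusted over the list alone, 4 and 0 with the tumour block), among them Calb1, which encodes the calcium-binding protein calbindin (0.72). There camera's adjusted p was 0.0468 (adjusted p = 0.153 with an estimated correlation). That call was lost with quantile normalization (0.0568), reference centring (0.106), a stricter filter (0.363) and array weights (0.059). It was also lost without the LBH589 6 h array of MP525 (0.0516), or the DMSO (0.139) or LBH589 (0.0983) 12 h array of MP567, or all arrays of MP567 (0.216). Calbindin's DMSO 12 h values lay at most 0.25 over the 25th percentile of their arrays, so its fold is uncertain. Leaving out 1 tumour ended the calls of Atf3, Sesn3, Cdkn1c, Bak1 and Calb1. In total 13 of 33 lists were called at 12 h, 6 higher and 7 lower, and none of the 13 with an estimated correlation. Fry called 19 lists, among them all of the 13 but cholesterol synthesis genes. The block called 14, adding neural stem and progenitor genes as higher (0.021), and 0 with an estimated correlation as well.

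**Figure D2:**
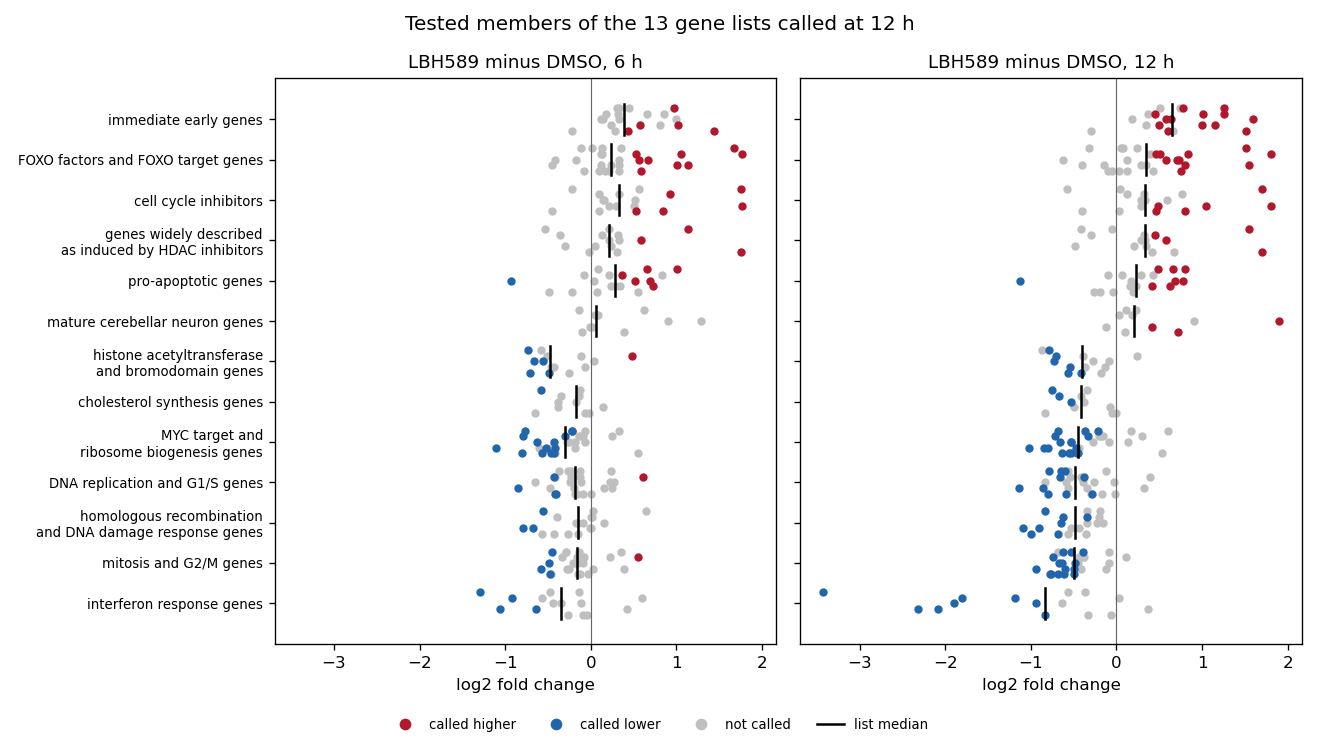
Log2 fold changes (LBH589 minus DMSO) of each tested member of the 13 gene lists called at 12 h, at 6 h on the left and 12 h on the right. Red and blue points passed an adjusted p of 0.05, grey points did not, and black bars mark list medians, which for interferon response genes were -0.35 at 6 h and -0.83 at 12 h.

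The remaining lists passed camera's threshold at neither time, apart from those already given as called at 12 h alone. Of the p53 target genes, 6 rose and 0 fell at 6 h and 8 rose and 0 fell at 12 h of 25 (adjusted over the list alone 7 and 0, then 9 and 1, and with the tumour block 12 and 5, then 14 and 6). The kinase gene Plk2 rose by 0.66 at 12 h. For endoplasmic reticulum stress and ATF4 genes, 6 rose and 2 fell at 6 h and 4 rose and 2 fell at 12 h of 19 (adjusted over the list alone 6 and 3, then 5 and 2, and with the tumour block 8 and 6, then 8 and 5), with Ddit3, which encodes the stress factor CHOP, at 1.24 and 1.21. Among heat shock genes, 2 rose and 1 fell at 6 h and 2 rose and 1 fell at 12 h of 12 (adjusted over the list alone 2 and 1, then 3 and 1, and with the tumour block 2 and 1, then 5 and 1). Hspd1, which encodes mitochondrial HSP60, was the one that fell (-0.40 and -0.59). Among oxidative stress and NRF2 genes, 2 rose and 1 fell at 6 h and 3 rose and 2 fell at 12 h of 12 (adjusted over the list alone 2 and 2, then 3 and 3, and with the tumour block 4 and 4, then 3 and 4), with Hmox1 at 0.84 and 1.03. Among antigen presentation genes, 2 rose and 0 fell at 6 h and 3 rose and 0 fell at 12 h of 13 (adjusted over the list alone 3 and 0, then 3 and 1, and with the tumour block 4 and 0, then 4 and 1), with the class I gene H2-K1 at 1.05 and 1.15. In the PI3K-AKT-mTOR list, 5 rose and 3 fell at 6 h and 5 rose and 2 fell at 12 h of 23 (adjusted over the list alone 5 and 3, then 5 and 2, and with the tumour block 8 and 4, then 7 and 5). Tsc2, an inhibitor of mTORC1, rose by 0.71 and 0.78. In the HDAC and sirtuin list, 5 rose and 2 fell at 6 h and 5 rose and 2 fell at 12 h of 18 (adjusted over the list alone 7 and 2, then 6 and 3, and with the tumour block 7 and 6, then 9 and 5). Among MYC network factors, 3 rose and 0 fell at 6 h and 1 rose and 0 fell at 12 h of 13 (adjusted over the list alone 3 and 0, then 1 and 0, and with the tumour block 4 and 1, then 5 and 2). Mxd1, an antagonist of MYC at its binding sites, rose by 1.0 and 0.93. Among anti-apoptotic genes, 0 rose and 1 fell at 6 h and 0 rose and 2 fell at 12 h of 11 (adjusted over the list alone 0 and 1, then 0 and 3, and with the tumour block 0 and 4, then 0 and 4), and Xiap changed by -0.64 at 12 h. Among glycolysis genes, 1 rose and 0 fell at 6 h and 0 rose and 1 fell at 12 h of 13 (adjusted over the list alone 1 and 0, then 0 and 1, and with the tumour block 4 and 1, then 1 and 3). Among commonly used reference genes, 0 rose and 1 fell at 6 h and 0 rose and 3 fell at 12 h of 10 (adjusted over the list alone 0 and 0, then 1 and 3, and with the tumour block 1 and 1, then 2 and 4), and Hprt changed by -0.60 at 12 h. For the lists from p53 targets to reference genes, camera's adjusted p lay between 0.0576 and 0.924, the lowest being that of p53 targets at 12 h. Leaving out 1 tumour ended the 6 h calls of Hspd1, Hmox1, Tsc2 and Mxd1 and the 12 h calls of Mxd1, Xiap and Hprt.

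Lineage genes moved in both directions. Among neural stem and progenitor genes, 5 rose and 1 fell at 6 h and 7 rose and 2 fell at 12 h of 18 (adjusted over the list alone 5 and 2, then 7 and 2, and with the tumour block 11 and 3, then 12 and 4). Sox9 (0.84 and 0.90) rose at both times, while Msi1, an RNA-binding protein of neural progenitors, fell (-1.02 and -1.04). Among neuronal genes, 3 rose and 2 fell at 6 h and 4 rose and 5 fell at 12 h of 31 (adjusted over the list alone 3 and 2, then 4 and 5, and with the tumour block 9 and 11, then 9 and 13), with Eno2 (0.98) and Vgf (0.93) higher at 12 h. In the granule neuron lineage and SHH pathway list, 1 rose and 2 fell at 6 h and 1 rose and 2 fell at 12 h of 20 (adjusted over the list alone 1 and 2, then 1 and 2, and with the tumour block 3 and 8, then 4 and 6). The pathway's transcription factor gene Gli1 rose (0.88 and 0.71), and Smo, another gene of the pathway, changed by -1.04 at 12 h. Of photoreceptor genes of Group 3 medulloblastoma, 0 rose and 2 fell at 6 h and 0 rose and 2 fell at 12 h of 17 (adjusted over the list alone 0 and 2, then 0 and 2, and with the tumour block 0 and 4, then 1 and 2), with Npr3 at -1.63 and -1.61. As to markers of other cell types, of the microglia and macrophage genes, 0 rose and 0 fell at 6 h and 1 rose and 0 fell at 12 h of 16 (adjusted over the list alone 0 and 0, then 1 and 0, and with the tumour block 0 and 0, then 2 and 3). The one at 12 h was Cd68 (0.71), whose call was lost without the DMSO 12 h array of MP525 (0.0531). Of astrocyte genes, 1 rose and 0 fell at 6 h and 1 rose and 0 fell at 12 h of 11 (adjusted over the list alone 1 and 0, then 1 and 0, and with the tumour block 1 and 2, then 2 and 3), the one at 12 h being Aldoc (1.40). Of oligodendrocyte genes, 1 rose and 0 fell at 6 h and 1 rose and 0 fell at 12 h of 11 (adjusted over the list alone 1 and 0, then 1 and 0, and with the tumour block 2 and 0, then 2 and 0), with Cnp at 0.76 and 1.02. Of endothelial genes, 1 rose and 0 fell at 6 h and 1 rose and 0 fell at 12 h of 11 (adjusted over the list alone 1 and 0, then 1 and 0, and with the tumour block 1 and 0, then 3 and 0), with Kdr at 0.81 at 6 h. Of fibroblast and mural cell genes, 0 rose and 0 fell at 6 h and 0 rose and 0 fell at 12 h of 12 (adjusted over the list alone 0 and 0, then 0 and 0, and with the tumour block 0 and 1, then 3 and 0). Only 1 erythroid gene was bright enough to test, so that list was not tested. For the lineage and cell type lists from neural stem to fibroblast genes, camera's adjusted p lay between 0.0786 and 0.908. Leaving out 1 tumour ended the 6 h calls of Sox9, Gli1, Npr3, Cnp and Kdr and the 12 h calls of Gli1, Smo, Eno2, Vgf and Cd68.

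The effects at 6 h and 12 h were closely alike across genes. The 6 h and 12 h log2 fold changes correlated at r = 0.876 (Spearman's rho 0.798) across the 18652 genes, which are not independent replicates, and at 0.827, 0.798 and 0.703 within MP525, MP567 and MP570. The comparisons share no arrays but share their tumours. With every probe set used, r was 0.788. Called at both times were 1137 higher genes, against 144.6 expected for independent lists, and 1093 lower genes, against 123.7, and none of the 2230 moved in opposite directions. Averaged over both times, 5607 genes changed (30.1%), 2925 higher and 2682 lower (limma adjusted p under 0.05), and 317 and 256 with a log2 change of at least 1. With the block 8566 were called, 4420 higher and 4146 lower, including 5602 of the 5607. The split was 2120 and 3827 after median centring and 4037 and 1968 after reference centring, and 3678 or 3308 genes were called without MP525 or MP570. The largest average rises were those of Cpt1a (2.86 ± 0.15), Hspa1b (2.56), Hspa1a (2.5), Slc8b1 (2.21 ± 0.09), Gas6 (2.13), Tspan17 (2.10), Rian (2.09) and Copz2 (2.04). The largest average falls were those of Olig3 (-2.43), Acsl5 (-2.41 ± 0.09), Usp18 (-2.36), Casd1 (-2.10), Arhgap42 (-2.04), Ubxn8 (-2.01), Ap4s1 (-1.97) and Parp12 (-1.89).

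**Figure D3:**
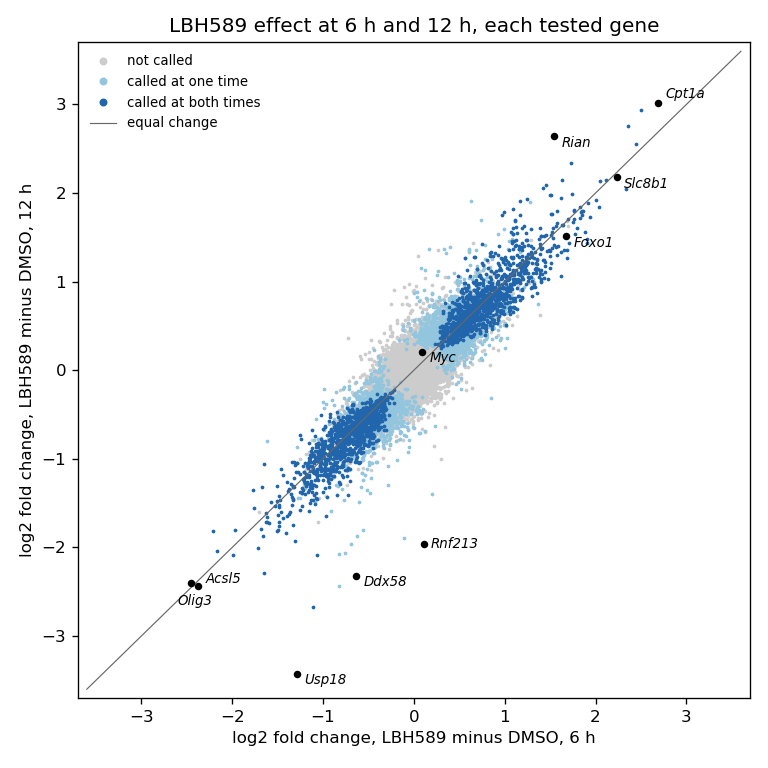
Log2 fold change (LBH589 minus DMSO) at 6 h on the x axis and 12 h on the y axis, a point for each of the 18652 tested genes, coloured by the times at which it was called, with the line of equal change. Most called genes lie near the line (r = 0.876), and Usp18, Ddx58 and Rnf213 lie below it.

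Whether the LBH589 effect itself differed between 12 h and 6 h was tested as an interaction. By list medians, interferon response, mitosis and DNA repair genes had a lower effect at 12 h than at 6 h, but none of these lists was called with an estimated correlation or with fry. The ubiquitin ligase gene Rnf213, which is induced by interferon, differed by -2.07 and Ddx58 by -1.68. Both had adjusted p of 0.0856 and 0.0764 by limma in the fit without a block, and passed the test with the tumour as a block (0.000689 and 0.00774) and as a random block (0.00262 and 0.00636). They also passed after median centring (0.0409 each) and without the DMSO 12 h array of MP567 (0.0118 each). Without the block, limma called 0 genes, while 490 had an unadjusted p under 0.05. For interferon response genes the median difference was -0.50, with 0 rising and 5 falling of 15 when adjusted over the list alone, and camera's adjusted p was 2.0e-13 (adjusted p = 0.137 with an estimated correlation). For mitosis and G2/M genes it was -0.39 (adjusted p = 1.7e-13, and 0.365 with an estimated correlation). For homologous recombination and DNA damage response genes it was -0.33 (2.5e-07, then 0.161), for DNA replication and G1/S genes -0.28 (9.6e-06, then 0.724) and for immediate early genes 0.20 (0.0116, then 0.365). With the block 8 lists were called, the added ones being fibroblast and mural cell (0.00588, higher), cholesterol synthesis (0.00594, lower) and glycolysis genes (0.04, lower), and 0 with an estimated correlation as well. The call of the immediate early list was lost without the DMSO 6 h array of MP525 (0.177), the DMSO 12 h (0.0575) or LBH589 12 h (0.268) array of MP567, or the LBH589 6 h array of MP570 (0.0575). That of the DNA replication list was lost without the LBH589 12 h array of MP570 (0.168). Leaving out the DMSO 12 h array of MP567 gave 2 gene calls and 8 lists, and leaving out the DMSO 6 h array of MP570 gave 8 lists. The other 28 lists did not pass camera's threshold for this difference without the block.

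In DMSO alone, interferon response genes rose from 6 to 12 h. Usp18 went from 8.81 ± 0.42 to 11.46 ± 0.55 (log2 values, mean ± SD, n = 3), Rnf213 from 8.04 ± 0.15 to 10.35 ± 0.46, and Ddx58 from 7.92 ± 0.18 to 9.92 ± 0.28. Their log2 changes were 2.65 ± 0.28, 2.31 ± 0.20 and 2.0 ± 0.15, and that of Parp12 was 2.20 ± 0.26 (limma adjusted p = 0.00504, 0.000759, 0.000313 and 0.0112). In LBH589 the same genes had changes of 0.51, 0.24, 0.32 and 0.63 over that time, none of which was called. The difference between the time courses is the interaction given above, called for Rnf213 and Ddx58 under the 4 settings named there and not in the fit without a block. These 4 were the only genes called in DMSO, all higher, and 412 had an unadjusted p under 0.05. With the block 58 were called, 41 higher and 17 lower, the next largest rise being that of Eif2ak2, which encodes the RNA-dependent kinase PKR (2.0, blocked adjusted p = 0.000871). The largest blocked falls were those of Slc7a3 (-0.92), Rny1 (-0.86), Chac1 (-0.80), Hspa1b (-0.78) and Hspb1 (-0.70). Of the 15 listed interferon response genes, 2 rose and 0 fell (12 and 0 adjusted over the list alone, 8 and 0 with the tumour block), with a median change of 0.88. Camera's adjusted p for that list was 6.6e-41, and the call held with an estimated correlation (adjusted p = 0.00362). Antigen presentation genes were higher by camera (7.2e-07, and adjusted p = 0.069 with an estimated correlation). Endoplasmic reticulum stress and ATF4 genes (4.0e-08), MYC target genes (6.0e-08) and heat shock genes (0.0314) were lower. For those 3, adjusted p = 0.15, adjusted p = 0.069 and adjusted p = 0.242 with an estimated correlation. No member of these 4 lists was called in DMSO without the block. With it 8 lists were called, adding cholesterol synthesis (0.000203) and neuronal genes (0.00217) as higher and immediate early genes (0.0165) as lower, none of which passed with an estimated correlation and no block (0.972, 0.972 and 0.407). All 4 gene calls were lost in a fit of only the DMSO arrays, and without MP525 or MP570. Usp18 and Parp12 were also lost without MP567 (0.093 and 0.18). Parp12 was lost too without the DMSO 6 h array of MP525 (adjusted p = 0.0771). Leaving out the DMSO 12 h array of MP567 gave 15 calls.

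**Figure D4:**
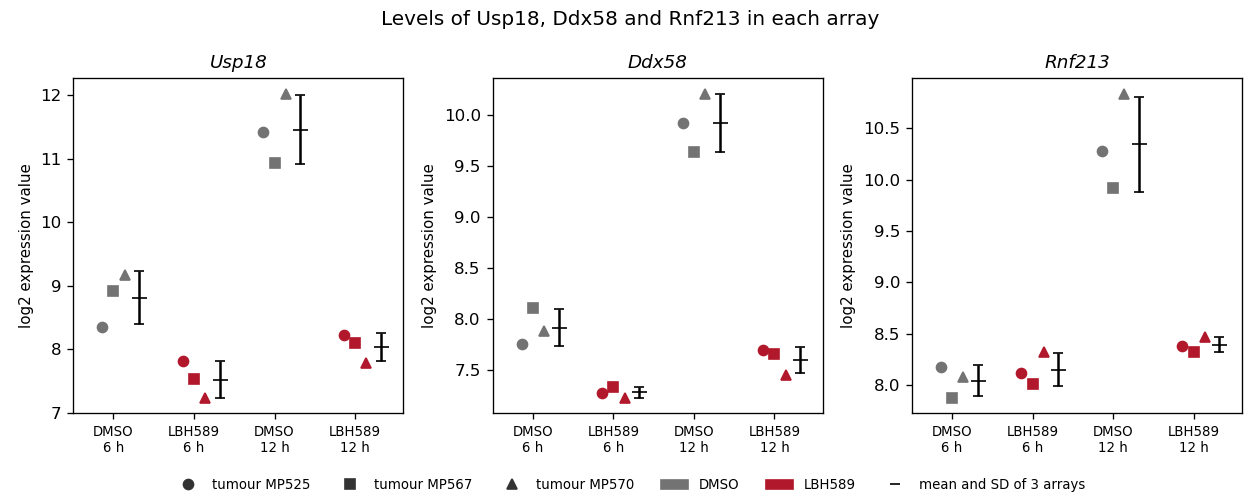
Log2 expression values of Usp18, Ddx58 and Rnf213 in each of the 12 arrays, by treatment and time, with the tumour shown by the symbol and the mean and SD of the 3 arrays of a group in black. All 3 tumours were higher in DMSO at 12 h than in any other group, for Usp18 with a mean of 11.46 against 8.81 in DMSO at 6 h and 8.04 in LBH589 at 12 h.

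In LBH589 alone, no gene was called between 6 and 12 h by limma, and 1415 had an unadjusted p under 0.05. With the tumour as a block 371 were called, 135 higher and 236 lower. The largest blocked rises were those of the collagenase gene Mmp13 (2.04), the acute phase gene Saa3 (1.98), the chemokine gene Ccl5 (1.89), Mmp3 (1.70) and Serpinb2 (1.44). The largest blocked falls were those of Chac1 (-1.09), the centromere gene Cenpl (-0.83), the transferrin receptor gene Tfrc (-0.80), Abracl (-0.77) and Zxda (-0.77). In DMSO, Mmp13, Saa3 and Ccl5 had changes of 0.80, 1.22 and 1.33 over the same time, with blocked adjusted p of 0.208, 0.00527 and 0.00146. The difference between the time courses was called for none of the 3 (blocked adjusted p = 0.209, 0.341 and 0.455). None of the 33 lists was called with an estimated correlation, and 9 were at the preset one. Mitosis and G2/M genes (median -0.34, camera adjusted p = 3.2e-14, and 0.22 with an estimated correlation), homologous recombination genes (-0.31, 1.1e-07, then 0.181) and DNA replication genes (-0.28, 6.5e-07, then 0.436) were lower. So were MYC target (1.4e-06, then 0.181), endoplasmic reticulum stress (6.2e-05, then 0.279) and reference genes (0.0231, then 0.22). Interferon response (0.000883, then 0.365), antigen presentation (0.00168, then 0.22) and mature cerebellar neuron genes (0.0448, then 0.22) were higher. With the block, fibroblast (0.0044, and 0.365 with an estimated correlation and no block) and immediate early genes (0.0292, then 0.565) were called as higher, while reference and mature cerebellar neuron genes were not (0.0501 for both). Of the 25 mitosis and G2/M genes, 0 rose and 0 fell (0 and 4 adjusted over the list alone, 0 and 12 with the tumour block). Reference centring gave 2 gene calls and moved the median change of all genes to 0.16. Leaving out the DMSO or the LBH589 12 h array of MP567 gave 1 call each.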

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

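Of the tests in this part, those of a scaling shift, of a single tumour and of a rise of microglia as large as that of interferon genes were chosen after the result was seen, as were the genes named.

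The LBH589 effect at 12 h differed from that at 6 h for 5 gene lists by camera's test of the difference itself at a preset correlation. All 5 calls were lost with an estimated correlation (0.137 to 0.724) and with fry (0.157 to 0.9). The median differences were -0.50 for interferon response genes, -0.39 for mitosis and G2/M genes, -0.33 for homologous recombination and DNA damage response genes, -0.28 for DNA replication and G1/S genes and 0.20 for immediate early genes. Without a block no single gene passed that test in the fit of all arrays as deposited. Rnf213 (-2.07) and Ddx58 (-1.68) passed with the tumour as a block or a random block, after median centring, and without the DMSO 12 h array of MP567. In the other splits of the arrays, up to 11 lists were called against 5 in the real one, and 6 of the 10 splits gave at least as many. Among the 4 splits that part every pair, the highest other was 5. For single genes without the block, the real split gave 0 calls and so did each of the 10. With 10 splits, no share under 0.05 can be had.

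Interferon response genes rose from 6 to 12 h in DMSO by a median of 0.88 (95% interval of the median 0.43 to 1.69, 15 genes) and by 0.32 (0.11 to 0.45) in LBH589. In 4 of 4 genes called in DMSO, all 3 tumours rose. Of the 10 splits of the DMSO arrays, 1, the real one, gave as many as 4 calls, and the highest other gave 0. With so few splits no share under 0.05 can be had. The DMSO 12 h arrays enter both this rise and the 12 h effect of LBH589, so the larger fall of these genes at 12 h carries the rise in DMSO.

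A scaling shift of the DMSO 12 h arrays was not seen. Array medians were alike as deposited, and all genes had a median change of 0.003 in DMSO, so the test that follows had little room to come out otherwise. The 1424 genes nearest in level to the list's members, matched on the LBH589 arrays, had a median change in DMSO of 0.01 with an upper end of the 95% interval of 0.0164, far below 0.442, which is 50% of the list's change. A change carried by a single tumour is argued against, since the lowest of the 3 tumours' medians was 0.697 (0.784 in MP525, 0.697 in MP567 and 1.23 in MP570). For the difference between the time courses, the list's adjusted p stayed at or below 5.8e-09 without any one tumour at the preset correlation. That call does not hold, with all tumours, at an estimated correlation (0.137) or with fry (0.157).

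Cells of another type could bring interferon transcripts into the cultures, and no sort or gate is named in the labels. Of the 16 tested microglia and macrophage genes, 12 lay above the median of the arrays, with the highest level for Lyz2 (9.12). A level above that median does not by itself show that such cells were present. Their median change in DMSO was -0.02 (95% interval -0.19 to 0.28). The 2 intervals lay 0.151 apart, so the median of these genes did not rise as much as that of interferon genes in these arrays. Both intervals run over genes, which are not independent replicates, and leave out the spread between tumours. They do not decide how the number of such cells changed. Whether a smaller rise took place cannot be told apart from none, because the upper end of the interval, 0.277, lies above 0.221, 25% of the interferon change.

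What stays open, and was not tested, is whether the tumour cells themselves began an interferon response in culture that LBH589 held down, whether few cells of another type made interferon without growing in number, and whether plating or handling triggered it. The design has no arrays before plating and no untreated cultures, so the time in DMSO and the time since plating go together.

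Probe sets that the array annotation does not list were outside the report's comparisons. Of 11216 tested, 282 were higher and 205 lower in LBH589 at 6 h, and 282 were higher and 411 lower at 12 h. They carry no gene name here, and no explanation was tested for them.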

How the results depend on the processing

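Only camera with an estimated correlation and the tumour as a block together was chosen after the data were seen, among the alternatives here.

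No value of a named gene or list that was called, as reported or under the alternative, reversed its direction under any alternative run. Uncalled values changed sign in 22 cases over 11 results, among them Hdac7, Foxo3, Hdac8 and Gapdh after a change of scaling. The larger side of the called genes did turn with the scaling, as after median centring, where 1163 were higher and 1760 lower at 6 h (1584 and 1364 as reported) and 2120 and 3827 over both times (2925 and 2682). With the tumour as a block, calls went to 6333 at 6 h, 6928 at 12 h, 8566 over both times, 2 for the difference between times, 58 in DMSO and 371 in LBH589, and 8 lists were called for the difference. This follows from removing the tumours' own levels from the spread. With the tumour as a random block (correlation 0.40), calls were 5493 at 6 h, 6087 at 12 h, 2 for the difference, 23 in DMSO and 25 in LBH589. Quantile normalization gave 7 calls in DMSO, median centring 2 for the difference, and reference centring 8 in DMSO and 2 in LBH589, and the cause was not tested. With every probe set, the correlation of the 6 h and 12 h effects was 0.788. A fit of only the DMSO arrays gave 0 calls, with fewer degrees of freedom. For the difference and for both times, a fit of only the arrays compared is the same as the one reported and was not run.

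With an estimated correlation, camera called 0 lists at 6 h, 0 at 12 h and 0 for the difference, and 0, 0 and 0 with the block added. Fry called 17 lists at 6 h, 19 at 12 h and 0 for the difference, and it asks another question than camera. Of the lists camera called at the preset correlation, fry lost none at 6 h. At 12 h it lost only cholesterol synthesis genes (fry adjusted p = 0.1).

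Without 1 array or 1 tumour, calls ranged from 879 to 2994 at 6 h, 1265 to 3370 at 12 h, 3308 to 5288 over both times, 0 to 2 for the difference, 0 to 15 in DMSO and 0 to 1 in LBH589. Lists called ranged from 6 to 12 at 6 h and 4 to 8 for the difference. The counts of 2 for the difference, 15 in DMSO, 1 in LBH589 and 8 lists came without the DMSO 12 h array of MP567. The 8 lists also came without the DMSO 6 h array of MP570, and the 1 in LBH589 also without the LBH589 12 h array of MP567. The 12 lists came without MP570, and fewer arrays leave fewer degrees of freedom.

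Of 301 results for named genes, 206 were called. Over 3900 values of them under other settings, 107 lost a call, 133 gained one and 0 reversed, and over 4515 with an array or tumour left out, 555 lost and 49 gained one. For lists, 64 of 1551 values lost a call and 46 gained one under other settings, and 18 and 48 of 1485 with an array or tumour left out. The direction split of called genes depends on the scaling, as the report gives. Dim genes were left out by the filter, so changes in them are not covered.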

Other observations

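All tests of hypotheses in this part had their outcome bounds written before the values they measure were seen, and the values of the imprinted cluster under other filters were added afterwards. The patterns and the genes named were noticed in the same data.

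Genes of the imprinted cluster from Meg3 to Mirg, which holds many microRNAs and small nucleolar RNAs, were higher in LBH589. Of 86 genes of the cluster in the reference table, 33 were tested, and the median change was 0.36 at 6 h (95% interval 0.17 to 0.56) and 0.41 at 12 h (0.22 to 0.82). At 12 h, 14 were called higher and 0 lower, and at 6 h 7 were called higher and 0 lower. A rise can itself bring a dim gene past the filter, so these 33 are not a neutral sample. Without the filter, 51 genes had a median of 0.41 at 6 h (0.29 to 0.55) and 0.41 at 12 h (0.23 to 0.63), with 44 and 48 higher by value. With a filter on the DMSO arrays alone, 24 genes had medians of 0.30 (0.06 to 0.55) and 0.31 (0.21 to 0.64), with 19 and 24 higher. The largest changes at 12 h were those of AF357425 (2.94), Rian (2.64) and Mir453 (2.15), and Meg3 itself had 0.01. Probe sets of small RNAs rising in general is argued against, since 321 small RNA genes outside the cluster had a median change of 0.01 with an upper end of 0.0516, below 0.207, which is 50% of the cluster's median. Among those, 8 were called higher and 6 lower. Without the filter the upper end was 0.024 over 514 such genes. The 3 members first noticed (AF357425, Mir453 and Rian) carrying the pattern alone is argued against too, as the remaining 30 had a median of 0.36 with a lower end of 0.218, and the lower end was 0.220 over 48 without the filter and 0.197 over 21 with the filter on DMSO arrays. Members of a cluster can be parts of 1 host transcript, so they are not independent measurements. A candidate explanation is a longer or more active transcript across the cluster under LBH589, which was not tested.

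Effects following the level in DMSO would show as dim genes rising and bright genes falling. Spearman's rho across genes, between the DMSO level in one tumour and the effect in the others, was -0.0556, -0.0139 and -0.0642 at 6 h and -0.254, -0.157 and -0.096 at 12 h for MP525, MP567 and MP570. The highest, -0.0139, argues against a trend at both times, while a weak one at 12 h stays open. Effects falling with the genomic length of genes had a rho of 0.00599 at 6 h and -0.0716 at 12 h over 16373 genes, and the tumours differed in sign at 12 h (0.0242, -0.136 and -0.0893), which argues against length as a cause. Genes are not independent replicates, so no p is given.

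Other splits of the arrays were compared with the real one by the number of calls. For LBH589 at 6 h, 1 of the 10 splits, the real one with 2948 calls, gave as many, and the highest other gave 0. For 12 h this was 1 of 10, with 3395 calls against 0. For lists at 6 h, 3 of 10 splits gave as many as the real 7, with a highest other of 9, and at 12 h 3 of 10 gave as many as the real 13, with a highest other of 15. Of the 4 splits that part every pair of a tumour, the highest other called 7 lists at 6 h and 9 at 12 h. Between times in LBH589, the real split gave 0 calls and so did all 10. With 10 splits a share under 0.05 cannot be had. For the effect over both times, 100 of the 200 splits were fitted, which were all 32 that part every pair of a tumour and others drawn at random that leave some pairs together. Only the real one gave as many as 5607 (1 of 100, and 1 of the 32). The highest other gave 6, and 0 among the 32, which argues against chance there but does not exclude it. Only the 32 keep the pairing, so the share cannot be very small. A split that mixes treatments also puts the effect of the drug into the spread, which lowers its calls.

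The tumours differed in level in all groups. MP525 had higher Mid2 (10.98 against 8.20 in the others), Crabp1 (12.12 against 9.23) and Atoh1 (11.02 against 8.18). MP567 had lower Xist (7.26 against 12.43) and Sox1 (7.16 against 9.55) and higher Eif2s3y (10.02 against 6.45) and Uty (9.30 against 5.81). MP570 had lower Tfap2a (5.67 against 9.54) and Sox2 (6.90 against 8.62) and higher Maob (10.21 against 7.21).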
